A study of Arabidopsis lyrata with 2 samples.

How the data were processed

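Small RNAs of 20 to 25 nt were sequenced on a SOLiD instrument from flowering tissues of Arabidopsis lyrata, an outcrossing relative of Arabidopsis thaliana, in 2 biological replicates that form 1 group. Per the labels' protocols, plants grew to rosettes at 22 °C under days of 16 hours, spent 6 weeks at 15 °C under days of 8 hours, and were then moved back to the first conditions. Total RNA was taken with a phenol-based reagent, small RNAs were separated on a gel cassette, and barcoded libraries were made with the instrument maker's small RNA kit, per the labels' protocols. The labels name both libraries as biological replicates and do not say how many plants went into each.

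The deposited files hold 1 record per read, a bead position and the read's colors, with no counts or normalized values. SOLiD reads each pair of neighbouring bases as 1 of 4 colors, and the first color after the known primer base fixes the first base of the RNA. No color was missing, all reads were 20 to 25 colors long, and abundant reads decoded to known microRNAs of that same length, so adapters had been removed and lengths chosen before the files were deposited. The software for these steps is not given in the sources used here. The library totals are therefore totals of 20 to 25-nt reads, not of all reads sequenced. No genome was used here, so reads were not filtered by a genome match and fragments of ribosomal and transfer RNA were kept. All values are shares of the deposited reads, or RPM, reads scaled to a total of 1000000 deposited reads per library.

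Identical color reads were tallied in each library with Python 3.11.15, numpy 2.4.6 and numba 0.67.0, and statistics came from scipy 1.17.1. The tally gave 48446876 reads in replicate 1 and 41731851 in replicate 2. The libraries shared 0 bead positions, where 2 separate slides would share about 2.06e+05 by chance, so both barcoded libraries were read on the same slide. Intervals are 95% Wilson intervals for shares and exact conditional binomial intervals for ratios of the libraries. A count of 0 allows up to 3 reads, which is 0.0619 RPM in replicate 1 and 0.0719 RPM in replicate 2. Reads made by PCR without molecular identifiers are not independent molecules, so intervals and limits cover counting error only.

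MicroRNAs were counted by exact sequence over the full length against 112 sequences of 86 families, written from Arabidopsis thaliana names before the data were examined. The list holds 25 families conserved among flowering plants, 55 limited to the Brassicaceae, 3 microRNA families in neither list and 3 trans-acting siRNAs. The conserved and limited families were compared by a two-sided permutation test with 100000 resamples on the difference of median log10(RPM + 0.1), and by a two-sided Fisher's exact test on the number of families with 3 or more reads in each library. Families are not independent replicates. The replicates were compared by the number of families over 2-fold apart among those with 100 or more reads in both libraries together, with Benjamini-Hochberg adjustment of the exact binomial p over these families. With 1 group, no test between conditions exists. On simulated color reads with 86 families, of which 20 were changed 4-fold, the ratio step recovered 20 and made 0 false calls, and 3 of 100 list tests without any difference gave p under 0.05. The simulated family reads varied by counting error alone and carried no base changes. They check the counting steps, not the ratios called in these data.

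The families named were fixed before the data were examined: the 12 most abundant conserved and the 10 most abundant Brassicaceae-limited families, the 3 with the largest ratio in each direction, the 10 most abundant 20 to 22-nt sequences further than 2 nt of shift from any listed one, and the trans-acting siRNAs. The rule left out structural RNAs from these sequences, which was not done, since no annotated sequence was used here. The alternatives were each replicate alone, distinct sequences in place of reads, 1 color mismatch, up to 2 nt of shift at either end, a pseudocount of 1 RPM, detection at 10 reads, a minimum of 10 reads for the ratio, and 2 other scalings. Sequences seen at least 2 times, the last 6 bases left free, and the removal of 4 families were added after seeing the data. The 4 planned results that need a genome (opposite strands by folded precursor, 24-nt reads outside genes, shared 24-nt loci and phased loci), along with adapter-bearing reads, are not reported here. A listed sequence in each of 4 microRNA families, and the listed siRNA of TAS1, had 0 reads in the files used here beside 100 or more reads that differ in the last 6 bases. Their counts of 0 were kept in the main values, and set no limit on how abundant these small RNAs were.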

Results

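The series holds 1 group, flowering tissues of Arabidopsis lyrata, with 2 biological replicates and 1 small RNA library from each. Replicate 1 had 48446876 reads of 20 to 25 nt and replicate 2 had 41731851. Distinct sequences numbered 35889657 and 31666523, or 74.1% and 75.9% of the reads. The design holds no comparison of conditions. It describes the small RNA classes of flowers and how far replicates differ.

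Small RNAs of 24 nt, the length of the siRNAs that direct DNA methylation in plants, were the largest class of the flower libraries. They took 47.2% ± 0.0217 of reads (SD, n = 2), and the next class, 23 nt, took 14.9% ± 0.0581. The 21-nt class, which holds most microRNAs and trans-acting siRNAs, took 11.3% ± 0.449. The 22-nt class took 13.0% ± 0.0625, the 25-nt class 8.89% ± 0.469 and the 20-nt class 4.64% ± 0.119. The gap between the 24-nt class and each other class was far larger than the spread between replicates.

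The first base differed between the size classes. Among 24-nt reads, 62.3% ± 0.528 began with A, 18.8% ± 0.156 with G, 10.8% ± 0.186 with C and 8.09% ± 0.499 with U (SD, n = 2). Among 21-nt reads, 26.3% ± 1.59 began with U and 40.8% ± 1.88 with A. An initial A is favoured by the Argonaute proteins that bind heterochromatic siRNAs, and an initial U by the one that binds most microRNAs. Among the 6 lengths, only 20 nt had U as its most frequent first base over reads, at 33.5% ± 0.231 against 31.0% ± 0.258 for A. Over distinct sequences the 5' U share of the 21-nt class was 19.2% ± 0.953, so the abundant 21-nt sequences began with U more often than the rare ones.

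**Figure D1:**
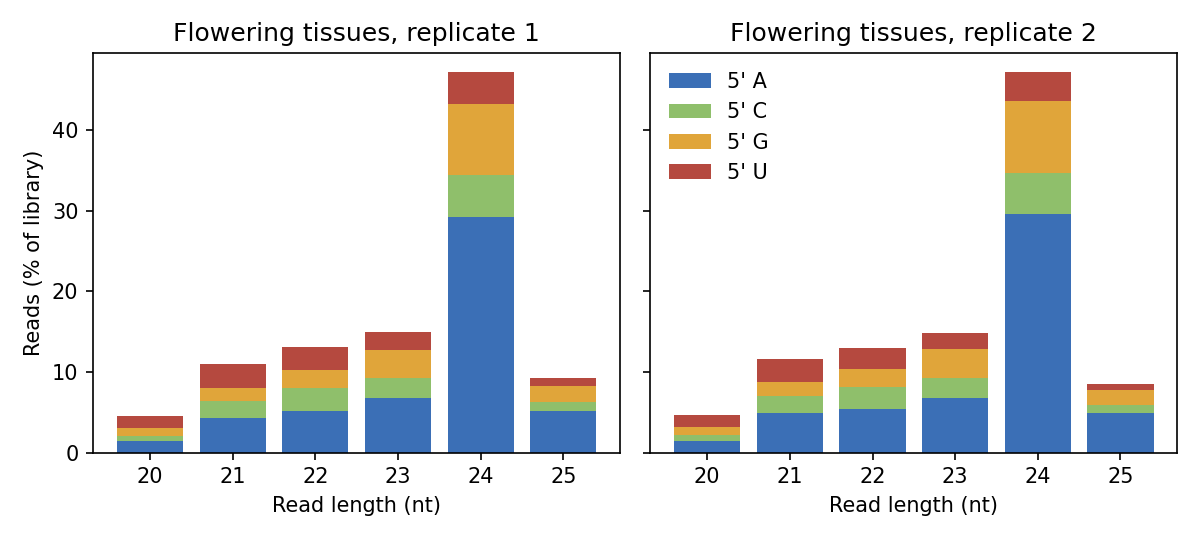
Read length (nt) against the share of each library's reads (%), 1 panel per replicate, with each bar split by the first base of the read. The 24-nt bar reaches 47.2% in both replicates and is mostly 5' A.

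The 24-nt class also held the most distinct sequences, 47.9% of the distinct sequences of a library on average. Each distinct 24-nt sequence was read 1.32 ± 0.0269 times on average, against 1.68 ± 0.0339 times for 21 nt (SD, n = 2). Of the distinct 24-nt sequences of replicate 1, 7.67% were also read in replicate 2, and they held 23.1% of its 24-nt reads. For 21 nt these values were 7.31% and 39.3%. In replicate 1, 88.5% of distinct 24-nt sequences were read once, so depth limits this overlap. Base changes near the 3' end add to the distinct sequences. The first 18 nt alone gave 14106532 distinct starts in replicate 1, 82.4% as many as full 24-nt sequences.

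Listed microRNAs made up a small part of the reads, and few families made up most of them. Exact matches took 1.01% of reads in replicate 1 (95% Wilson interval 1.00 to 1.01) and 1.36% in replicate 2 (1.36 to 1.36). The families miR158, miR172, miR156, miR167 and miR171, 5 of the 83 listed, held 84.7% ± 3.67 of microRNA reads (SD, n = 2). The share rose to 1.52% with 1 color mismatch allowed and to 1.86% with the last 6 bases left free, so the exact match leaves out reads that differ by 1 color or in their last bases.

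Among conserved families, miR172, miR156 and miR167 were the most abundant. By mean, miR172, which acts on AP2-like floral regulators, came first at 2541 RPM ± 1464 (SD, n = 2), a place that rests on its 3577 RPM in replicate 2. In replicate 1 it had 1506 RPM, below miR156 with 2066 RPM and miR167 with 1755 RPM. That order depends on exact matching. With the last 6 bases left free, replicate 1 had 2739 RPM of miR172, 2720 RPM of miR156 and 2396 RPM of miR167. Over both replicates, exact matches of miR172 were followed by miR156, which acts on SPL genes of phase change, at 2286 ± 312 RPM. Then came miR167, which acts on auxin response factors needed for stamen and ovule growth, at 2047 ± 413 RPM. Next came miR171 with targets among GRAS genes at 735 ± 82.5 RPM, miR169 with NF-YA targets at 651 ± 25.3 RPM, and miR159 with GAMYB-like targets of the anther at 291 ± 21.2 RPM. The growth-related miR396, which acts on GRF genes, reached 168 ± 34.1 RPM. The organ boundary regulator miR164, with NAC targets, reached 109.6 ± 12.3 RPM, and miR166, with HD-ZIP III targets of leaf polarity, 100.8 ± 64.3 RPM. Of the remaining named families, miR390, which triggers trans-acting siRNAs, reached 48.7 ± 4.88 RPM, the sulfate-responsive miR395 46.4 ± 13.9 RPM, and miR162, which acts on the Dicer of microRNA processing, 31.1 ± 6.16 RPM. These levels are of exact sequences. With the last 6 bases left free, 8 of the 12 families had over 1.5 times their exact RPM, and miR159, at 1272 ± 23.8 RPM or 4.37 times its exact level, lay above miR169 at 829.3 ± 87.7 RPM.

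**Figure D2:**
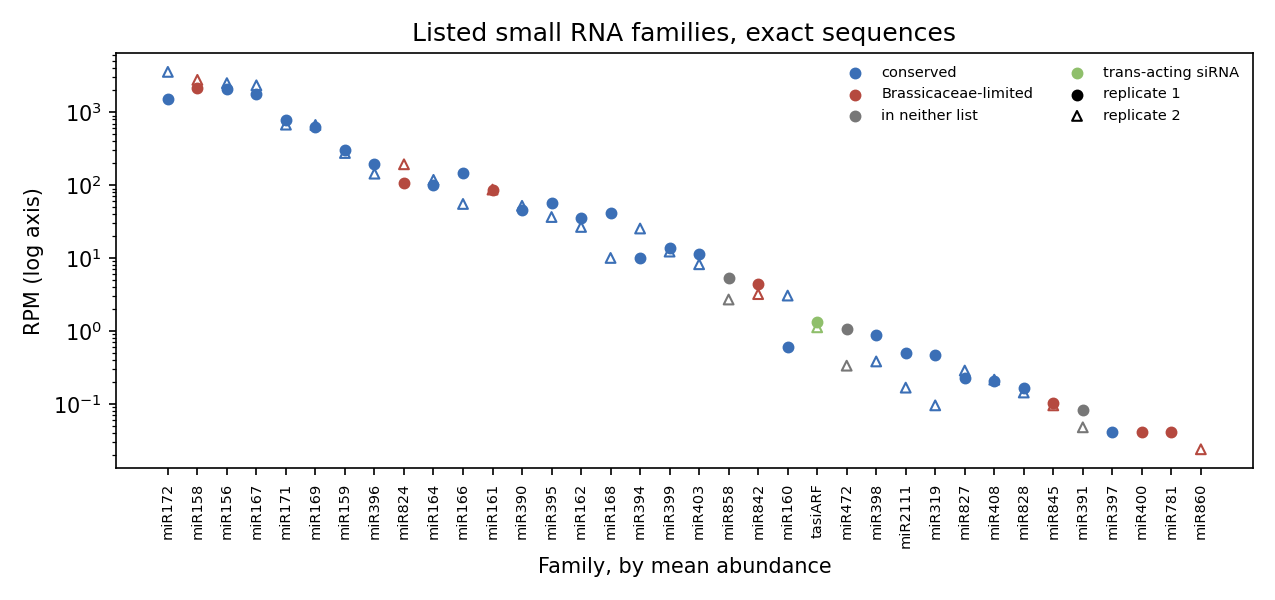
RPM (log axis) of each listed family with at least 1 read, ordered by mean abundance, with filled circles for replicate 1, open triangles for replicate 2 and color for the list. A replicate with 0 reads of a family has no point. The families range from 2541 RPM for miR172 down to single reads.

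Of 55 families limited to the Brassicaceae, 5 had 3 or more exact reads in each library. The highest by mean was miR158 at 2465 RPM ± 445 (SD, n = 2), with 2150 RPM in replicate 1 and 2780 RPM in replicate 2, followed by miR824, which acts on the MADS-box gene AGL16, at 150.3 ± 60.9 RPM, miR161, with pentatricopeptide repeat targets, at 86.3 ± 1.10 RPM, and miR842 at 3.82 ± 0.867 RPM. The fifth, miR845, had 5 and 4 exact reads. With the last 6 bases left free, miR824 had 2.17 times its exact RPM, miR161 2.79 times and miR842 2.53 times, while miR845 had 966 and 737 reads and miR860 102 and 64. Below them, miR400 and miR781 had 2 and 0 each, and miR860 had 0 and 1. The other 47 of 55 limited families had 0 exact reads in both libraries as used here. For 46 of them this allows up to 0.0619 RPM in replicate 1 and 0.0719 RPM in replicate 2 of the exact listed sequence. It sets no limit on the family, as 2 cases chosen after their values were seen show: miR846 had 31 and 16 reads with up to 2 nt of shift, and a relative of the listed miR839 sequence with T1C and T10C, positions counted from 1 at its 5' end, had 1964 and 1175 reads. For 1 family, which had reads with other last bases, it sets no limit on the listed sequence either.

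Conserved families were higher than limited ones by 2.55 in median log10(RPM + 0.1) in replicate 1 and by 2.41 in replicate 2. The median of the limited families was 0 RPM in both libraries, against 35.5 and 25.5 RPM for the conserved ones, so the pseudocount sets the size of this difference, which was 1.43 with a pseudocount of 1 RPM. The two-sided permutation p was 1e-05 in each library, the smallest that 100000 resamples can give. Of 25 conserved families 23 had 3 or more reads in each library, against 5 of 55 limited families (Fisher's exact test, two-sided, p = 3.6e-13). The listed sequences are those of Arabidopsis thaliana, so a family whose sequence differs by a base in Arabidopsis lyrata can count as undetected. Many conserved families had more than 1 listed sequence, but among limited families only miR161 and miR845 did. Conserved families thus had more chances of an exact match, which neither test takes into account.

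The replicates differed by more than 2-fold in 5 of the 23 families with 100 or more reads. The auxin-related miR160 was 5.12-fold higher in replicate 2 (95% counting interval 3.40 to 7.96), miR394, which acts on a leaf and meristem F-box gene, was 2.53-fold higher (2.27 to 2.82), and miR172 was 2.38-fold higher (2.35 to 2.40). In the other direction, miR168, which acts on the Argonaute of the microRNA pathway, was 4.14-fold lower in replicate 2 (3.73 to 4.61), and miR166 was 2.64-fold lower (2.52 to 2.77). The next lower family, miR858 with MYB targets, was 1.99-fold lower (1.59 to 2.50). The median absolute log2 ratio was 0.41 over the 23 families, against 0.03 and 0.04 between alternate panels of the slide within replicates 1 and 2, and 21 of 23 ratios lay beyond counting error at an adjusted p under 0.05 by the exact binomial test.

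These ratios depend on how reads are matched and scaled. With the last 6 bases left free, the log2 ratio of replicate 2 to replicate 1 moved from 2.36 to -0.35 for miR160, from 1.34 to 0.36 for miR394, from 1.25 to 0.81 for miR172, from -2.05 to -1.16 for miR168, and from -0.99 to -0.60 for miR858, while that of miR166 went from -1.40 to -1.38. With 1 color mismatch allowed, none of the 5 stayed over 2-fold apart: the log2 ratios were 0.35 for miR160, 0.40 for miR394, 0.84 for miR172, 0.06 for miR168 and -0.84 for miR166. Of the 5 families over 2-fold apart as exact sequences, 3 were higher in replicate 2 and 2 lower. With the last 6 bases free, 5 were over 2-fold apart, 0 higher and 5 lower, of which 2, miR166 and miR168, were among the first 5. Scaled to microRNA reads, 5 families were over 2-fold apart, 1 higher and 4 lower, of which 3 were among the first 5, and the median log2 ratio of all 23 went from -0.15 to -0.58.

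**Figure D3:**
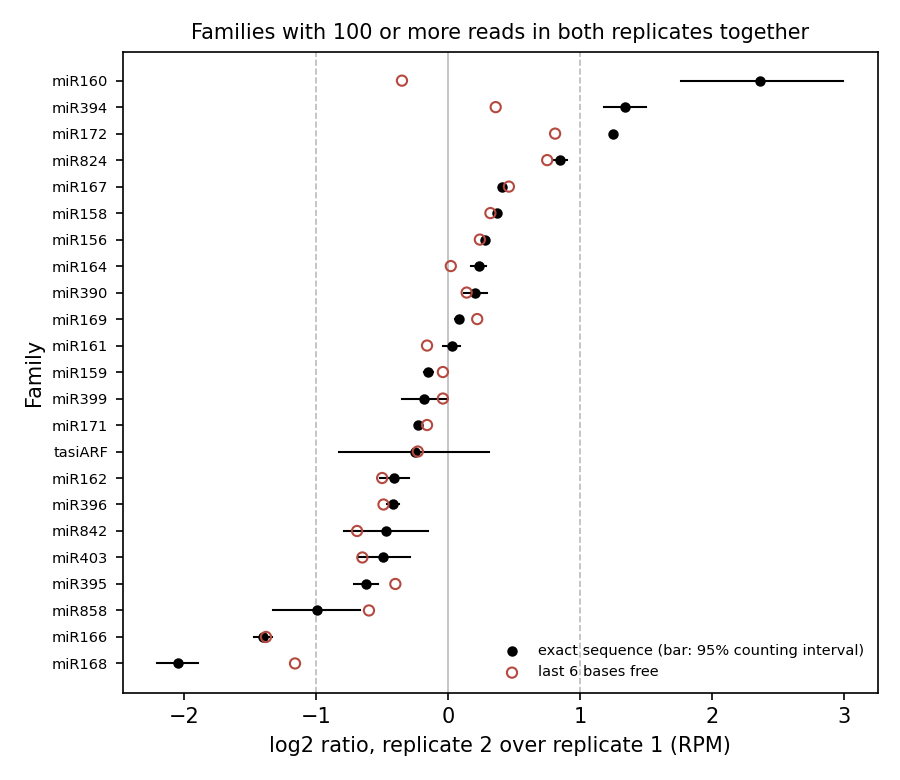
The log2 ratio of replicate 2 to replicate 1 for the 23 families with 100 or more reads, with black points for exact sequences, bars for 95% counting intervals and open red points for counts with the last 6 bases left free. Dashed lines mark 2-fold; miR160 crosses from 2.36 to -0.35 when the last bases are free.

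The most abundant 20 to 22-nt sequences outside the list were of 2 kinds. Of the 10, 6 were within 2 base changes of a listed sequence, with positions counted from 1 at the 5' end of the listed one. In 5 of the 6, every change lay in the last 6 bases of the sequence, where base changes were frequent among abundant small RNAs. In replicate 1, the 21-nt median was 9.30% of unchanged reads at position 16, 2.33% at position 18 and 1.38% at position 20. All 5 lay above such shares of their nearest listed sequences. These had 729 RPM for miR171, 179 RPM for miR159, 86.3 RPM for miR161 and 0 RPM for the siRNA of TAS1. What gave rise to the 5 was not tested. TGATTGAGCCGCGCCAATACC, miR171 with T20C, had 436.6 RPM ± 15.4 (SD, n = 2). TTTGGATTGAAGGGAACTCTA, miR159 with G16A, had 427 ± 13.9 RPM, and TTTGGATTGAAGGGAGCCCTA, miR159 with T18C, had 206 ± 21.3 RPM. CGGCTCTGATACCAGTTGATG, miR845 with A15G, had 420.0 ± 35.2 RPM, and TGAAAGTGACTACATCGGGGGT, miR161 with T21G and 1 more base at its 3' end, had 203 ± 53.2 RPM. TTCTAAGTCCAACATAGCTAA, with G19T and T20A against a listed trans-acting siRNA of TAS1, had 239 ± 41.7 RPM.

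The other 4 had no listed relative within 4 base changes. GTCGTTGTAGTATAGTGGTAAG, which starts like the 5' end of plant aspartate tRNA, was the most abundant at 572 RPM ± 454 (SD, n = 2), with 893 RPM in replicate 1 and 251.0 RPM in replicate 2. GCGCAAGTGAAATACCACTA, which resembles plant large-subunit ribosomal RNA, had 302 ± 11.5 RPM. CTTGATAGTGAGAAAGACCCA had 216 ± 21.6 RPM and ATGGCTAGAGTGACTAGACCCG had 196 ± 22.5 RPM. Their places in the genome were not analysed here.

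Of the listed trans-acting siRNAs, those of TAS3 alone had exact matches. The TAS3 siRNAs that act on auxin response factors had 1.23 RPM ± 0.152 (SD, n = 2), from 65 and 47 reads, and 5.94 ± 0.676 RPM with the last 6 bases left free. Their ratio between replicates, 0.839 (95% counting interval 0.564 to 1.24), did not differ beyond counting error. The listed siRNAs of TAS1 and TAS2 had 0 exact reads in both libraries as used here, and that of TAS1 had 15198 and 10172 reads with its last 6 bases left free. Most of these, 12998 and 8733 reads, were the 1 sequence with G19T and T20A named above.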

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

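Conserved families stayed above limited ones under all settings run, by 1.43 to 2.83 in median log10, with the pseudocount of 1 RPM lowest. The share of families detected stayed higher by 68.7 to 88.1 percentage points. Both differences had p under the threshold each time. No setting admits reads with a single base change before the last 6 bases. The settings therefore do not test whether limited families were missed through such changes in Arabidopsis lyrata. Over distinct sequences the 24-nt share was 47.9%, the 21-nt share 9.03%, the 5' A share of 24-nt reads 61.5% and the 5' U share of 21-nt reads 19.2%. Over sequences seen at least 2 times, chosen after seeing the data, these were 46.2%, 16.1%, 63.7% and 35.0%. The microRNA share was 1.52% with 1 color mismatch and, chosen after seeing the data, 1.86% with the last 6 bases free. Families over 2-fold apart numbered 9 of 30 with a minimum of 10 reads and 1 of 26 with 1 color mismatch. Otherwise they numbered 5 or 6, of 23 to 32 families with enough reads under the setting. The cause was not tested. With a single replicate, the 24-nt share was 47.2% in each, the 21-nt share ran from 11.0% to 11.7%, the 5' A share from 62.0% to 62.7%, the 5' U share from 25.2% to 27.5% and the microRNA share from 1.01% to 1.36%. The count over 2-fold needs both replicates. No paired analysis was possible because there is 1 group. Not run were the alternatives on adapter matching, genome matches, structural RNAs and all settings of the results that need a genome. Depth limits listed sequences near 0.0619 RPM and the overlap of 24-nt sequences between replicates.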

Other observations

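The tests of the 3 patterns below were chosen after the result was seen, except those on adjacent color changes, on changes before the last base in the longer read and on reversed sequences, which were set down before their results. The list of opposite strands, the families named from it and the 24-nt sequence named were also chosen after the values were seen.

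The opposite strand of a microRNA duplex is usually short-lived. Opposite strands of 15 families were written from Arabidopsis thaliana names, with no precursor of Arabidopsis lyrata used here. They held over 10% of the exact reads of both strands, by the mean of the replicates, in 4 families, and under 2% in 10, from 0.0182% for miR156 to 1.98% for miR171. With the last 6 bases of both strands left free, these counts were 4 and 7. The 5 highest as exact reads are given here, with shares that depend on how reads are matched. For miR408 the opposite strand held 93.9% ± 1.35 of the exact reads of both strands (SD, n = 2). This came from 185 and 119 reads against only 10 and 9 of the listed strand. With the last 6 bases of both strands left free, the listed strand had 18 reads in each replicate. The opposite strand then held 94.0% and 90.7% in replicates 1 and 2. For miR160 it held 94.8% ± 4.07 as exact reads, from 1208 and 1451 reads against 29 and 128 of the listed strand, but 55.5% and 68.8% with the last 6 bases free, where the listed strand had 1583 and 1071 reads. For miR168 it held 45.7% and 75.8% as exact reads, and 23.5% and 36.6% with the last 6 bases free. The opposite strand took 19.6% ± 3.52 of exact reads for miR390 and 2.15% ± 0.427 for miR167, against 15.8% and 12.6%, and 4.76% and 3.78%, with the last 6 bases free.

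Pairing between 24-nt reads had a local peak at the 2-nt 3' overhangs that Dicer enzymes leave, for which no test was run. A partner of the same length overlapping by 22 nt from the first base existed for 10.3% of 24-nt reads in replicate 1 and 9.08% in replicate 2. These shares lay above those at 20 nt of overlap, 9.83% and 8.13%, at 21 nt, 9.12% and 7.71%, and at 23 nt, 7.72% and 6.78%, but below those at 19 nt, a 5-nt overhang, 11.5% and 9.18%. Distinct sequences with a partner had no peak. At overlaps of 20, 21, 22 and 23 nt they numbered 812144, 673796, 655435 and 431036 in replicate 1, and 584124, 499076, 495191 and 325355 in replicate 2, with the smallest step from 21 to 22 nt. Among 21-nt reads, the share fell across overlaps of 18, 19 and 20 nt, from 8.66% to 7.24% and 5.96% in replicate 1 and from 7.30% to 6.89% and 6.40% in replicate 2. The most abundant 24-nt sequence, AGAGAAATTGTTAAAAATGCCCCT, had 110.7 RPM ± 8.97 (SD, n = 2).

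Toward the 3' end, abundant small RNAs carried many single-base changes, which began abruptly at the 6th base from that end: for 21-nt sequences with 1000 or more reads, the median share of changed reads was 0.0862% of the unchanged ones at position 15 and 9.30% at position 16 in replicate 1, and 0.0891% and 9.65% in replicate 2. Of the 10 sets of 1 length in 1 library, 3 had their highest share at that base, and 7 at the last base, among them 22 nt with 8.66% and 10.7% in replicates 1 and 2, while the first base, at 1.02% and 0.912% for 21 nt, was not weighed here. Before the last base, single color errors are argued against. They would spell a base change in about 33.3% of adjacent double color changes, and the median was 95.3% (95% bootstrap interval 94.7 to 96.1). For gene copies that differ, the most frequent change fell to a median 0.0548 times its share (0.00849 to 0.164) in the read 1 nt longer. Sequences with a base change at least as frequent as themselves, at either length, had been left out. This argues against gene copies for the less frequent changes kept, and leaves the more frequent ones untested. At the last base, where a change alters 1 color alone, color errors and gene copies both stay open. In the read 1 nt longer, that color was changed at 0.422 times its share (0.284 to 0.586). The most frequent last-base change had 0.816 times its share there (0.459 to 1.58). A candidate explanation for the start at the 6th base is that the last 6 bases were copied with errors while the libraries were made. Leaving out the last base, the steepest rise lay there in 70.3% of 360 sequences (interval 65.4 to 74.8). This was 84.4% of 205 at 21 nt and 42.9% of 14 at 23 nt. It was 52.8% at 20 nt, 53.3% at 22 nt and 51.2% at 24 nt. A sequence abundant in both libraries is counted in each, and the intervals take these entries as independent. The 6th base was picked from these same profiles, so the count describes the pattern and tests no cause. In the longer form of 66 pairs of lengths, the steepest rise lay at the 6th base from the 3' end in 28. It lay at the 7th, its place if fixed from the 5' end, in 16. Matching whole profiles of these pairs favoured the 3' end in 43.9% (32.6 to 55.9), which decides nothing. No biological explanation beyond gene copies was tested.

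The families over 2-fold apart between the replicates were the second pattern. Counting error is argued against, since 0 of the 23 families were over 2-fold apart between alternate slide panels of either library, which hold fewer reads. That 3' ends were chosen differently in library construction could neither be excluded nor shown: with the last 6 bases free, 2 of the 5 families, miR166 and miR168, stayed over 2-fold apart, and the log2 ratios of the other 3 came to lie between -0.35 and 0.81. Sequences counted in 1 family with the last 6 bases free moved apart between the replicates. Over 19 families, the median SD of their log2 ratios was 0.74 (interval 0.55 to 0.87), against 0.25 between alternate slide panels. These ratios ran from -6.46 to 4.25 for miR168, -3.79 to 2.34 for miR160 and -3.02 to 3.11 for miR172. They ran from -1.08 to 1.35 for miR394 and from -3.19 to -0.41 for miR166. What spread them was not tested. The log2 ratio of miR166 as a family was -1.40 with exact matches and -1.38 with the last 6 bases free. It was -1.12 with up to 2 nt of shift and -0.84 with 1 color mismatch. A difference between the plants of both replicates stays open, as untested.

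The third pattern is a set of base-changed relatives of Brassicaceae-limited sequences that were themselves barely read. Of 51 such sequences 5 had a relative within 2 base changes and with 30 or more reads in each library: miR845 with A15G (19143 and 18569 reads), miR839 with T1C and T10C (1964 and 1175), miR860 with G18A (91 and 54), miR840 with G6A (77 and 36) and miR825 with A6G (58 and 50). Reversed sequences had 0 such relatives (Fisher's exact test, two-sided, p = 5.6e-02), so chance neighbours cannot be told apart from true relatives at these numbers. By definition, miscopied last 6 bases cannot give relatives changed before them, which are 4 of the 5, so no test was needed there. For miR860 with G18A, the test assumed that a miscopy would be outnumbered by its source. This relative held 89.2% and 84.4% of all reads with its bases before the last 6 (95% exact interval of the lower 73.1 to 92.2). The assumption may fail in these libraries, so these shares do not decide whether miscopied last bases gave this relative. The listed miR160 sequence had 29 and 128 exact reads, among 1583 and 1071 with the last 6 bases left free. Sequence differences between both Arabidopsis species are a possible explanation that was not tested, since no genome was used here.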
